A study of Mus musculus with 16 samples.

How the data were processed

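Liver RNA was measured in C57BL/6 mice, an inbred laboratory strain. The mice drank control water or water with antibiotics and then received, by oral gavage, 1 dose of a slurry made from standard chow or from fast food. Per the labels' protocols, livers were taken 4 h after the gavage, RNA was extracted with a QIAGEN kit and checked on a Bioanalyzer, and poly(A) libraries were made with the Illumina TruSeq mRNA kit and read as single reads of 50 bases. The antibiotics, their doses and the length of treatment are not given in the sources used here. The 16 libraries fall into 4 groups of 4 by their titles, and replicates are numbered within each group. The labels say that mice were assigned at random but not that each replicate number is a separate mouse. If it were not, the p-values would measure only the spread between these samples.

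The deposited values are raw counts of reads per gene, whole numbers that sum to a different total in each library (8954378 to 18954655). The submitters' processing notes name FastQC, cutadapt, STAR, HTSeq, DESeq2, edgeR and the genome build GRCm38.p6, without versions. The annotation release, the strand setting of the counting and its treatment of reads with several matches are not given in the sources used here. Counts of near-identical paralogs (the Mup, Gst, Cyp2c, Cyp4a, Saa and H2 families) and of overlapping or antisense genes such as Hectd2os are therefore uncertain. The table held 25006 Ensembl gene identifiers, of which 24942 matched a symbol in the reference annotation and had coordinates in GENCODE M21 (GRCm38), given here 1-based. The 13 mitochondrially encoded genes had a count of 0 in all 16 libraries, so they could not serve as a measure of RNA quality.

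Everything that follows was computed from the deposited counts. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 13180 genes, and library sizes were scaled with TMM factors. edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with a mean for each of the 4 groups to all 16 libraries (robust dispersion, common biological coefficient of variation 0.222). Contrasts gave the effect of the meal in each water, the effect of the water with each meal, and their interaction, all two-sided. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The standard error printed with a log2 fold change is the absolute fold change divided by the square root of the F statistic. CPM values are counts scaled by library size with TMM factors, printed with their SD over 4 libraries.

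A total of 35 gene lists with 496 genes (pathways of liver metabolism and stress, and markers of other cell types) was fixed before the data were examined, as were the rule for named genes and the alternatives marked as such, and 490 of those genes were in the table. The 28 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and again with the correlation estimated from the data. No list passed in any comparison with the estimated correlation, so camera's calls of lists hold only under the preset value. Counts of list members called over all genes are given beside counts adjusted over the list alone.

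For each comparison of 2 groups the rule for named genes took the 6 largest rises and the 6 largest falls among genes past the threshold with a mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a predicted or clone name. It added up to 4 members of lowest p from each list that passed or had at least 3 members called, and 18 genes of lipid, glucose, bile acid, xenobiotic and acute phase metabolism whether called or not. For the interaction it took the 8 genes of lowest p, and for overlaps up to 6 genes called in both comparisons. Some genes that the rule took are not reported here. The other 240 called genes over the 5 comparisons, counted once in each, are all named.

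The alternatives fixed at that time were DESeq2 1.42.0, RLE factors, no filter on low counts, a minimum mean of 10 counts in every group, fits to the 2 groups compared (not for the interaction), the replicate number as a block, and leaving out each library in turn. For the lists they also included an estimated correlation and fry. Alternatives chosen after seeing the data left out 3 libraries with high acute phase transcripts, or handled the share of counts in 4 features that take ribosomal RNA-like (rRNA-like) reads, Lars2, Mir6236, Gm20594 and Mir6240. That share entered as a covariate or as a model term splitting the libraries at 1% of counts. Each side of this split was also fitted, over all groups with at least 2 libraries on it.

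The method was tested on simulated counts, drawn with the mean of each gene over all libraries, the real library sizes and the fitted dispersions, and with 200 changed genes. In the simulation of the meal effect in control water, over 12978 genes, 13.3% of genes changed 1.5-fold, 56.8% of those changed 2-fold and 83.1% of those changed 4-fold were called. For the meal effect in antibiotic water, over 13008 genes, the shares were 15%, 48.1% and 89.8%. For the antibiotic effect they were 16.7%, 53.1% and 84.7% with the chow meal (13014 genes) and 23.3%, 48.1% and 89.8% with the fast food meal (13027 genes). For the interaction, over 12982 genes, they were 3.33%, 19.8% and 81.4%. Unchanged genes made up 6.36% of the calls in the simulation of the meal effect in control water, above the threshold of 5%, and 1.94%, 1.9%, 3.64% and 2.94% in the others in the order given. Replicates of a group differed by far more than sampling noise (the lowest chi-square per degree of freedom of any pair was 14.4), so no library was treated as a duplicate. Every library had little Xist (at most 1.42 CPM) and transcripts of the Y-linked gene Ddx3y (at least 128 CPM).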

Results

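Poly(A) RNA of mouse liver was counted in 16 libraries, 4 from each combination of meal and drinking water. The comparisons ask how hepatic transcripts differ within hours of a fast food meal and whether that difference depends on treatment with antibiotics. Total counts ran from 8954378 to 18954655 per library. The share of counts in 4 rRNA-like features was 0.12% to 0.587% in 9 libraries and 2.45% to 8.42% in the other 7. All 4 fast food control libraries had a low share, as did chow control replicates 3 and 4, chow antibiotic replicates 1 and 3, and fast food antibiotic replicate 3. Acute phase transcripts were highest in chow control replicate 2, chow antibiotic replicate 4 and fast food antibiotic replicate 2 within their groups, with list scores (mean log2 deviation from the average library) of 1.08, 2.13 and 1.85.

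The first principal component held 38.8% of the variance. It ran from 36.5 to 74.1 in the chow antibiotic libraries and from -33.4 to -2.44 in the 8 control-water libraries. Fast food antibiotic replicates 1, 3 and 4 lay between -16.1 and -10 on it, and replicate 2 of that group lay at 45.4.

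**Figure D1:**
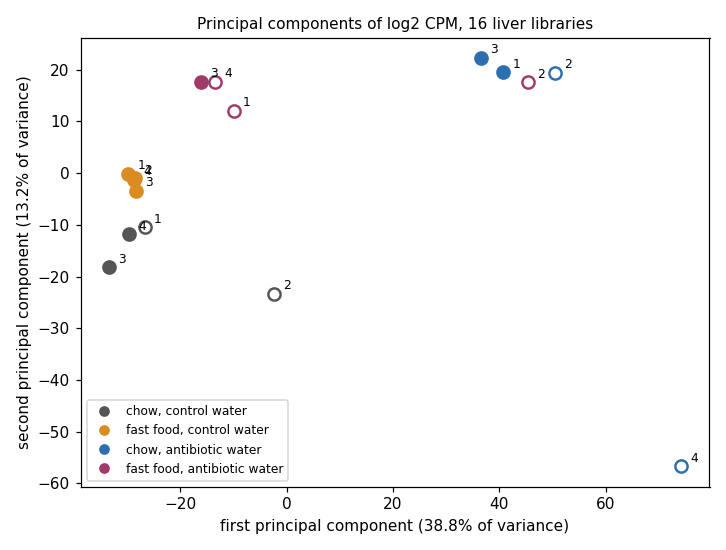
Position of each liver library on the first (38.8% of variance) and second (13.2%) principal component of log2 CPM, coloured by meal and water and numbered by replicate, with open circles for libraries with at least 1% of counts in rRNA-like features and filled circles for the rest. Fast food antibiotic replicate 2, at 45.4 on the first component, lies within the range of the chow antibiotic libraries (36.5 to 74.1).

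In mice on control water, the fast food meal differed from chow at 76 of 13180 genes. Slc22a7, an organic anion transporter, was 8.14 ± 1.73 CPM after fast food and 1.06 ± 0.734 CPM after chow (SD, n = 4 each), a log2 fold change of 2.85 ± 0.46 (SE, edgeR adjusted p = 0.0132). The other 5 of the 6 largest rises under the naming rule were in the ammonium transporter gene Rhbg (1.6 ± 0.33), Keg1 (1.44 ± 0.29), Tstd1 (1.36 ± 0.27), the carboxylesterase gene Ces3b (1.33 ± 0.25) and Omd (1.23 ± 0.26). The glutathione transferase gene Gstp1 fell from 743 ± 116 to 219 ± 71.9 CPM (log2 fold change -1.76 ± 0.29, adjusted p = 0.016). Csad, an enzyme of taurine synthesis (-2.11 ± 0.36), Gstm3 (-1.70 ± 0.36), Gabbr2 (-1.60 ± 0.21), Col15a1 (-1.59 ± 0.27) and Lrp11 (-1.52 ± 0.32) also fell. These 12 genes showed no overlap between the libraries of the 2 meals.

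Antioxidant genes of the NRF2 list were lower after fast food in control water (camera adjusted p = 0.000919, adjusted p = 0.155 with an estimated correlation). Of its 13 tested members 2 were called over all genes, Gstm1 (-1.06 ± 0.13) and Ephx1 (-1.09 ± 0.20), and 3 adjusted over the list alone. Amino acid catabolism and urea cycle genes were higher as a list (adjusted p = 0.000288, adjusted p = 0.413 with an estimated correlation). Among them 2 of 17 were called, including Otc (0.69 ± 0.12), and 2 adjusted over the list alone. The circadian clock list was higher (adjusted p = 0.00487, adjusted p = 0.413 with an estimated correlation), with Per2 (0.93 ± 0.17) called and 6 of 18 adjusted over the list alone. Bile acid synthesis was higher (adjusted p = 0.0163, adjusted p = 0.413 with an estimated correlation), with Slc27a5 (0.69 ± 0.13) called and 3 of 14 adjusted over the list alone. Bile acid synthesis did not pass camera without chow control replicate 2 (adjusted p = 0.053) or fast food control replicate 1 (0.0711). Pericentral hepatocyte genes were higher (adjusted p = 0.00129, adjusted p = 0.413 with an estimated correlation), with Rhbg called and 5 of 13 adjusted over the list alone. The CAR and PXR xenobiotic list was higher (adjusted p = 0.00404, adjusted p = 0.413 with an estimated correlation) although it went both ways. Cyp2c54 rose (1.12 ± 0.24) and Gstm3 fell, and adjusted over the list alone 5 of 22 were higher and 1 lower.

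No member was called over all genes in the 4 other lists that passed, all higher after fast food in control water. They were choline and trimethylamine metabolism (camera adjusted p = 0.000919, adjusted p = 0.155 with an estimated correlation), the unfolded protein response (adjusted p = 0.000209, adjusted p = 0.413 with an estimated correlation), cholesterol synthesis (adjusted p = 0.0021, adjusted p = 0.767 with an estimated correlation) and stellate cell markers (adjusted p = 0.0461, adjusted p = 0.544 with an estimated correlation). Adjusted over the list alone they held 4 of 16, 0 of 20, 0 of 22 and 1 of 12 calls. The stellate cell list did not pass camera without chow control replicate 1 (adjusted p = 0.109), chow control replicate 4 (0.082), fast food control replicate 2 (0.0552), fast food control replicate 3 (0.128) or fast food control replicate 4 (0.0719). Several of the fixed genes had values that did not pass, among them Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.24 ± 1.01, adjusted p = 0.713), Fasn (-0.38 ± 0.34, 0.75) and Pck1 (0.10 ± 0.39, 0.948).

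Of 13180 genes tested, 76 passed, 32 higher and 44 lower after fast food in control water, and 36 changed at least 2-fold (1515 genes had an unadjusted p under 0.05). For 75 of the 76 the groups did not overlap, as for 10.3% of all genes against 2.86% by chance. The count depended on every library. Without chow control replicates 1, 2, 3 and 4 it was 12, 25, 19 and 42, and without fast food control replicates 1, 2, 3 and 4 it was 17, 11, 20 and 19. Of the 22 called genes named, 3 (Gabbr2, Gstm1 and Nt5c2) kept their call without each library in turn. For the other 19 the highest adjusted p of these fits is given with the library left out. Ces3b (0.0888), Cyp2c54 (0.157), Per2 (0.078), Rhbg (0.136), Slc22a7 (0.063) and Slc27a5 (0.104) had theirs without chow control replicate 1. Cd9 (0.0929), Col15a1 (0.0775), Csad (0.0775), Ephx1 (0.0929), Gstp1 (0.0775), Nt5dc2 (0.153), Omd (0.137) and Otc (0.0775) had theirs without fast food control replicate 2. Cul7 (0.112) and Gstm3 (0.145) had theirs without fast food control replicate 3. Keg1 (0.126), Lrp11 (0.149) and Tstd1 (0.12) had theirs without fast food control replicate 4. The count was 305 with DESeq2 (169 higher, 136 lower), 365 in a fit to these 2 groups and 160 without the 3 libraries with high acute phase transcripts. It was 22 with the rRNA-like share as a covariate, 17 with the split as a model term, and 154 among the low-share libraries (2 chow, 4 fast food), of which 55 were among the 76. The high-share side held chow libraries only. More genes were higher than lower with DESeq2, in the fit to 2 groups (206 against 159) and without chow control replicate 4 (24 against 18) or fast food control replicate 2 (6 against 5).

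In mice on antibiotic water, transcripts of fatty acid oxidation were higher after fast food than after chow. All 26 tested PPAR-alpha targets had positive fold changes, and 14 were called, 19 adjusted over the list alone (camera adjusted p = 1.65e-07, adjusted p = 0.663 with an estimated correlation). The hepatokine gene Fgf21 was 5.06 ± 3.07 CPM after fast food and 0.327 ± 0.32 CPM after chow (SD, n = 4 each), a log2 fold change of 3.77 ± 0.65 (edgeR adjusted p = 0.004). The fatty acid carrier gene Fabp1 rose (2.63 ± 0.48), as did the lipid droplet gene Plin2 (1.66 ± 0.29) and the carnitine transporter gene Slc22a5 (1.03 ± 0.22). The other large rises under the naming rule were in Inhbe (3.55 ± 0.58), Chad (3.15 ± 0.53), the ketone body enzyme gene Bdh1 (3.02 ± 0.40), the antisense transcript Hectd2os (2.86 ± 0.69) and Stap1 (2.77 ± 0.50).

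Fatty acid synthesis genes went both ways after fast food in antibiotic water. Of 17 tested, 6 were higher and 1 lower (6 and 2 adjusted over the list alone). The higher ones included Fads2 (2.27 ± 0.38), Elovl5 (2.17 ± 0.43), Acacb (0.97 ± 0.20) and Fads1 (0.66 ± 0.15). The list's median was -0.0619 and its mean 0.37, and camera's direction was up (adjusted p = 0.717). The desaturase gene Scd1 rose (3.29 ± 1.02, adjusted p = 0.0493). Of 12 stellate cell markers 4 were higher, and 4 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.227). They were Col1a1 (2.04 ± 0.49), Col3a1 (1.80 ± 0.39), Col1a2 (0.83 ± 0.24) and Rgs5 (0.57 ± 0.17). Heat shock genes were higher (3 of 10, 4 adjusted over the list alone, camera adjusted p = 0.0363, adjusted p = 0.663 with an estimated correlation), with Hsph1 (1.93 ± 0.33), Hspa1b (1.87 ± 0.59) and Dnaja1 (1.03 ± 0.13). The heat shock list did not pass camera without chow antibiotic replicate 1 (adjusted p = 0.124), chow antibiotic replicate 3 (0.0633) or fast food antibiotic replicate 1 (0.0762).

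Immediate early genes were lower after fast food in antibiotic water, with negative fold changes for all 13. Over all genes 4 were called, Ier2 (-1.72 ± 0.39), Myc (-2.13 ± 0.54), Nr4a1 (-2.61 ± 0.79) and Ier3 (-4.46 ± 1.33, not called by DESeq2), and 12 adjusted over the list alone (camera adjusted p = 6e-07, adjusted p = 0.663 with an estimated correlation). Acute phase genes were lower (3 of 22 on either adjustment, adjusted p = 0.000394, adjusted p = 0.663 with an estimated correlation), with Cp (-1.0 ± 0.21), Itih3 (-0.88 ± 0.22) and the hepcidin gene Hamp (-1.05 ± 0.29). Chow antibiotic replicate 4 and fast food antibiotic replicate 2 had the highest acute phase scores of these groups. The acute phase list did not pass camera without chow antibiotic replicate 4 (adjusted p = 0.0536). Mean acute phase scores differed by -0.915 with all libraries, -0.456 without chow antibiotic replicate 4, -1.58 without fast food antibiotic replicate 2 and -0.59 without fast food antibiotic replicate 4. Neutrophil markers, 3 and too few for a test of the list, were lower (1 over all genes, 3 adjusted over the list alone), with a median of -3.35 and of -0.61 without chow antibiotic replicate 4. The call over all genes was lost without that library or without fast food antibiotic replicate 1, 3 or 4. Amino acid catabolism genes were lower (3 of 17 on either adjustment, adjusted p = 0.0389, adjusted p = 0.663 with an estimated correlation), with Got1 (-1.34 ± 0.29), Prodh (-0.77 ± 0.17) and Tdo2 (-0.50 ± 0.16). The amino acid list did not pass camera without chow antibiotic replicate 2 (adjusted p = 0.106), chow antibiotic replicate 3 (0.0916), fast food antibiotic replicate 2 (0.278) or fast food antibiotic replicate 3 (0.0524). Mean amino acid scores differed by -0.236 with all libraries and -0.152 without fast food antibiotic replicate 2. The unfolded protein list was lower (2 of 20 on either adjustment, adjusted p = 0.0372, adjusted p = 0.663 with an estimated correlation), its called members being the stress transcription factor genes Atf4 (-0.75 ± 0.20) and Atf3. The unfolded protein list did not pass camera without chow antibiotic replicate 1 (adjusted p = 0.0654), chow antibiotic replicate 2 (0.0804), chow antibiotic replicate 3 (0.0685), fast food antibiotic replicate 1 (0.0776), fast food antibiotic replicate 3 (0.0704) or fast food antibiotic replicate 4 (0.0916). Mean unfolded protein scores differed by -0.467 with all libraries and -0.703 without fast food antibiotic replicate 2. The cholesterol synthesis list was lower with 0 of 22 called on either adjustment (adjusted p = 2.25e-05, adjusted p = 0.663 with an estimated correlation). The cholesterol list passed camera whichever single library was left out. Mean cholesterol scores differed by -0.926 with all libraries and -0.576 without fast food antibiotic replicate 1.

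The oxysterol hydroxylase gene Cyp7b1 fell from 569.9 ± 216 to 128 ± 21.7 CPM after fast food in antibiotic water (-2.16 ± 0.28, adjusted p = 0.000695). Bile acid synthesis genes went both ways, 1 higher and 3 lower of 14 (4 and 4 adjusted over the list alone, camera adjusted p = 0.18), with Baat (-0.78 ± 0.15), Cyp27a1 (-0.68 ± 0.15) and Akr1c6 (0.66 ± 0.21). Of 16 choline and trimethylamine genes 5 were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.0588). They included Dmgdh (-1.06 ± 0.20), Bhmt2 (-0.51 ± 0.14) and Chdh (0.82 ± 0.16). Other lists with at least 3 members called did not pass camera. The transport list (1 higher and 2 lower of 15, 3 and 3 adjusted over the list alone, adjusted p = 0.96, median -0.0114, mean 0.0731, camera direction down) held Klb (-0.71 ± 0.17), Slc10a1 (-0.53 ± 0.14) and Abcb4 (0.60 ± 0.19). The CAR and PXR list (2 higher and 1 lower of 22, 7 and 3 adjusted over the list alone, adjusted p = 0.96) held Cyp2a5 (1.30 ± 0.31), Aldh1a1 (0.85 ± 0.27) and Cyp2c50 (-0.77 ± 0.25). The clock list (2 higher and 1 lower of 18, 4 and 2 adjusted over the list alone, adjusted p = 0.717) held Bhlhe41 (1.95 ± 0.48), Arntl (-1.68 ± 0.45) and Per2. Among genes with no overlap between the groups, the 6 largest falls under the naming rule were in Atf3 (-3.08 ± 0.90), Thbs1 (-2.57 ± 0.63), Myom3 (-2.55 ± 0.44), Socs2 (-2.27 ± 0.51), Tes (-2.22 ± 0.30) and Serpina12 (-2.19 ± 0.59).

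In antibiotic water 1800 genes passed, 1026 higher and 774 lower after fast food, and 14.5% of all genes showed no overlap of the groups against 2.86% by chance. The count was 1086, 3042, 842 and 697 without fast food antibiotic replicates 1, 2, 3 and 4, and 965 without chow antibiotic replicate 2. Of 58 called genes named, 31 kept their call without each library in turn, and 27 lost it in at least 1 of these fits. Their highest adjusted p is given with the library left out. Col1a2 (0.0882) had its own without chow antibiotic replicate 2. Nr4a1 (0.14) had its own without chow antibiotic replicate 3. Atf3 (0.115) and Ier3 (0.218) had theirs without chow antibiotic replicate 4. Hspa1b (0.142) and Serpina12 (0.0645) had theirs without fast food antibiotic replicate 1. Abcb4 (0.13), Akr1c6 (0.18), Aldh1a1 (0.172), Bhlhe41 (0.0677), Cyp2a5 (0.0504), Hectd2os (0.0575), Myc (0.0603), Scd1 (0.156), Tdo2 (0.141) and Thbs1 (0.063) had theirs without fast food antibiotic replicate 3. Arntl (0.0829), Atf4 (0.0855), Bhmt2 (0.0856), Col1a1 (0.0506), Cul7 (0.0744), Cyp2c50 (0.135), Hamp (0.0906), Itih3 (0.0594), Nt5dc2 (0.156), Rgs5 (0.138) and Slc10a1 (0.0625) had theirs without fast food antibiotic replicate 4. A fit to these 2 groups called 229 genes and 11 of the 58, and omission of the 3 libraries with high acute phase transcripts gave 3206. More genes were lower than higher without these 3 libraries (1675 against 1531) and without chow antibiotic replicate 1 (797 against 706). Among the high-share libraries (2 chow, 3 fast food) edgeR called 1 gene, with 2238 at an unadjusted p under 0.05, and the low-share side held a single fast food antibiotic library.

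The meal effects in the 2 waters share no library. They had a correlation of 0.119 across 13180 genes, which are not independent replicates, and of -0.0369 with the split as a model term and -0.00164 without the 3 libraries with high acute phase transcripts. Both comparisons called 11 genes, of which 1 rose in both, 2 fell in both and 8 went in opposite directions, where independent lists would share 2.49 rises and 2.58 falls. They shared 67 with DESeq2, 66 without the 3 libraries, 4 with the share as a covariate and 3 with the split as a model term. The clock gene Per2 rose in control water and in antibiotic water (0.86 ± 0.17). Cd9 (-0.89 ± 0.17 and -1.50 ± 0.17) and Nt5c2 (-1.01 ± 0.15 and -0.68 ± 0.15) fell in both. Cul7 (-0.88 ± 0.17 and 0.68 ± 0.17) and Nt5dc2 (-1.12 ± 0.24 and 0.82 ± 0.26) fell in control water and rose in antibiotic water.

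The meal effect differed between the waters by a test of the interaction at 519 genes, 311 with a more positive effect in antibiotic water and 208 with a more negative one. Among the 8 genes of lowest p, Cyp7b1 had the largest difference (-3.15 ± 0.39 on the log2 scale, edgeR adjusted p = 0.00199). Bcl2l11, which promotes apoptosis (-1.52 ± 0.19), Gpld1 (-1.29 ± 0.18) and the glucuronosyltransferase gene Ugt2a3 (-1.33 ± 0.19) also had more negative effects in antibiotic water. Nfe2l1 (1.06 ± 0.14), Pgm3 (1.78 ± 0.25), the nucleotide synthesis gene Prps2 (1.53 ± 0.22) and the chemokine gene Ccl25 (1.62 ± 0.24) had more positive ones. Fgf21 differed by 4.86 (adjusted p = 0.00732).

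PPAR-alpha targets had more positive meal effects in antibiotic water (6 of 26, 13 adjusted over the list alone, camera adjusted p = 3.25e-07, adjusted p = 0.527 with an estimated correlation). Cholesterol synthesis had more negative ones (1 of 22 on either adjustment, adjusted p = 1.35e-07, adjusted p = 0.542 with an estimated correlation). So had choline and trimethylamine genes, with 4 lower and 1 higher of 16 (7 and 1 adjusted over the list alone, adjusted p = 0.000222, adjusted p = 0.234 with an estimated correlation). Amino acid catabolism (3 of 17, 6 adjusted over the list alone, adjusted p = 2.33e-05, adjusted p = 0.527 with an estimated correlation) and bile acid synthesis (3 of 14, 4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0121, adjusted p = 0.527 with an estimated correlation) had more negative effects. Of 10 lists that passed, the others were the unfolded protein response (adjusted p = 2.33e-05, adjusted p = 0.527 with an estimated correlation), immediate early genes (adjusted p = 5.78e-05, adjusted p = 0.527 with an estimated correlation) and the acute phase list (adjusted p = 0.0156, adjusted p = 0.713 with an estimated correlation), all more negative. Heat shock genes (adjusted p = 0.0156, adjusted p = 0.544 with an estimated correlation) and antigen presentation (adjusted p = 0.0443, adjusted p = 0.664 with an estimated correlation) were more positive. Of these 5 lists, members were called over all genes in heat shock alone (2 of 10). Adjusted over the list alone there were 0 of 20, 2 of 13, 0 of 22, 4 of 10 and 2 of 14. Bile acid synthesis did not pass camera without fast food antibiotic replicate 2 (adjusted p = 0.0636). The acute phase interaction did not pass camera without chow control replicate 3 (adjusted p = 0.0859), chow control replicate 4 (0.065), chow antibiotic replicate 4 (0.473), fast food antibiotic replicate 1 (0.0618), fast food antibiotic replicate 3 (0.0629) or fast food antibiotic replicate 4 (0.14). The interaction of mean acute phase scores was -0.659 with all libraries, -1.08 without chow control replicate 2, -0.199 without chow antibiotic replicate 4, -1.33 without fast food antibiotic replicate 2 and -0.333 without fast food antibiotic replicate 4. Antigen presentation did not pass camera without chow control replicate 3 (adjusted p = 0.385), fast food control replicate 1 (0.0864), fast food control replicate 3 (0.103), chow antibiotic replicate 1 (0.0798), chow antibiotic replicate 2 (0.105), fast food antibiotic replicate 1 (0.124) or fast food antibiotic replicate 4 (0.0587). The interaction of mean antigen presentation scores was 0.746 with all libraries and 0.434 without chow control replicate 3. The heat shock interaction did not pass camera without chow control replicate 3 (adjusted p = 0.0859), fast food control replicate 4 (0.0543) or chow antibiotic replicate 1 (0.0743).

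At an unadjusted p under 0.05 the interaction held 2785 genes. The count of 519 was 328, 1494, 307 and 164 without fast food antibiotic replicates 1, 2, 3 and 4, and 327, 264 and 324 without chow antibiotic replicates 1, 2 and 3. It was 174 and 290 without chow control replicates 1 and 2, and 224, 219 and 187 without fast food control replicates 1, 2 and 3. DESeq2 called 1120, the rRNA-like share as a covariate left 143, the split as a model term left 262, and omission of the 3 libraries with high acute phase transcripts gave 1851. More effects were negative than positive in that last fit (936 against 915) and without chow antibiotic replicate 1 (177 against 150). The 8 genes of lowest p kept their call in all of these fits. No side of the split held 2 libraries of every group.

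With the chow meal, antibiotic water was followed by higher sterol synthesis transcripts, lower fatty acid oxidation transcripts and lower transcripts of macrophages, interferon response and antigen presentation. Of 22 cholesterol synthesis and uptake genes 20 were higher on either adjustment (camera adjusted p = 1.06e-12, adjusted p = 0.331 with an estimated correlation). Lss was 85.9 ± 28.5 CPM with antibiotic and 16.9 ± 0.765 CPM with control water (SD, n = 4 each), a log2 fold change of 2.35 ± 0.33 (edgeR adjusted p = 0.000289). Stard4 (1.79 ± 0.30) and Dhcr7 (1.22 ± 0.18) also rose. Of 26 PPAR-alpha targets 19 were lower, 20 adjusted over the list alone (adjusted p = 2e-11, adjusted p = 0.331 with an estimated correlation). Fabp1 (-4.12 ± 0.51), Fgf21 (-4.08 ± 0.65), the thioesterase gene Acot2 (-3.08 ± 0.36), Plin2 (-2.76 ± 0.30), Slc22a5 (-1.59 ± 0.22) and Cyp4a14 (-1.10 ± 0.35) fell.

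Of 26 interferon response genes 16 were lower with antibiotic water and chow, 18 adjusted over the list alone (camera adjusted p = 2.31e-07, adjusted p = 0.373 with an estimated correlation), among them Ifit3 (-2.31 ± 0.37), Psmb9 (-2.23 ± 0.35), Irf7 (-1.57 ± 0.22) and Bst2 (-1.02 ± 0.18). The interferon score of chow antibiotic replicate 4 was 0.491, above those of chow control replicates 1, 2 and 4 (0.0686, 0.449 and 0.465), while the other chow antibiotic libraries had -0.97, -1.18 and -1.06. Of 14 antigen presentation genes 11 were lower, 12 adjusted over the list alone (adjusted p = 8.21e-07, adjusted p = 0.331 with an estimated correlation). They included H2-Ab1 (-3.29 ± 0.63), the class II transactivator gene Ciita (-3.04 ± 0.53), Tap1 (-1.65 ± 0.29) and Tap2 (-0.95 ± 0.15). Markers of B and plasma cells, which also express class II genes, were lower (2 of 2, too few for a test of the list, median -2.60), and both were called without each library in turn. Of 13 Kupffer cell and macrophage markers 10 were lower, 11 adjusted over the list alone (adjusted p = 2.4e-05, adjusted p = 0.367 with an estimated correlation). Folr2 was 1.64 ± 0.691 CPM with antibiotic and 7.91 ± 2.01 CPM with control water (-2.21 ± 0.29, adjusted p = 0.000105), and Ccr2 (-1.89 ± 0.36), Cd5l (-1.78 ± 0.31) and Timd4 (-1.58 ± 0.26) fell. The median log2 fold change was -1.08 over these markers and -0.0265 over 10 sinusoidal endothelial markers (1 lower on either adjustment, mean 0.0757, camera direction up, adjusted p = 0.941). Erythroid markers were lower (2 of 7 on either adjustment, adjusted p = 0.0293, adjusted p = 0.638 with an estimated correlation), with Car1 (-4.62 ± 0.69) and Alas2 (-1.48 ± 0.33). The erythroid list did not pass camera without chow control replicate 3 (adjusted p = 0.0706), chow control replicate 4 (0.0647) or chow antibiotic replicate 1 (0.123).

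Choline and trimethylamine genes were higher with antibiotic water and chow, 9 higher and 3 lower of 16, 10 and 3 adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.331 with an estimated correlation). Fmo2 (2.97 ± 0.28) and Dmgdh (1.84 ± 0.21) rose and Chdh (-1.01 ± 0.16) fell. Amino acid catabolism genes were higher (11 of 17, 13 adjusted over the list alone, adjusted p = 7.9e-06, adjusted p = 0.331 with an estimated correlation), with Got1 (2.64 ± 0.30), Prodh (0.89 ± 0.17) and the urea cycle gene Cps1 (0.69 ± 0.14). Genes of gluconeogenesis and the fasting hormone response were higher (7 of 12 on either adjustment, adjusted p = 0.00563, adjusted p = 0.331 with an estimated correlation). Igfbp1 was 2335 ± 1024 CPM with antibiotic and 199 ± 183 CPM with control water (3.55 ± 0.86), Tat (1.86 ± 0.40), Ppargc1a (1.45 ± 0.37) and Sds (1.03 ± 0.21) rose, and the gluconeogenic gene Pck1 had a fold change of 0.0403 ± 0.39 (adjusted p = 0.953).

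Stress and immediate early transcripts were higher as lists with antibiotic water and chow. Of 13 immediate early genes 8 were higher, 11 adjusted over the list alone (camera adjusted p = 5.3e-06, adjusted p = 0.331 with an estimated correlation), with Myc (2.24 ± 0.54), Ier2 (1.71 ± 0.39), Dusp1 (1.72 ± 0.46) and Btg2 (2.71 ± 0.73). The unfolded protein list was higher (4 of 20, 3 adjusted over the list alone, adjusted p = 0.00649, adjusted p = 0.638 with an estimated correlation), with Atf4 (0.97 ± 0.20), Atf3 (3.04 ± 0.89), Chac1 (2.48 ± 0.72) and Asns (1.56 ± 0.53). The acute phase list was higher, with 3 higher and 1 lower of 22, 3 and 0 adjusted over the list alone (adjusted p = 0.00281, adjusted p = 0.638 with an estimated correlation). Hamp (1.39 ± 0.29), Itih3 (1.17 ± 0.22) and Cp (0.94 ± 0.21) rose and Saa4 (-1.66 ± 0.57) fell, and the highest acute phase scores were in chow antibiotic replicate 4 and chow control replicate 2. The acute phase list did not pass camera without chow antibiotic replicate 4 (adjusted p = 0.156). Mean acute phase scores differed by 0.923 with all libraries and 0.463 without chow antibiotic replicate 4. Over 3 neutrophil markers, of which 1 was higher adjusted over the list alone, the median was 2.44, and it was -0.0204 without chow antibiotic replicate 4. Heat shock genes did not pass as a list (4 of 10 lower, 5 adjusted over the list alone, camera adjusted p = 0.0577), and Dnaja1 (-1.25 ± 0.13), Hsph1 (-1.85 ± 0.33), Hsp90aa1 (-1.33 ± 0.27) and Hspa1b (-1.88 ± 0.58) fell.

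Among genes with no overlap between the groups, 5 of the 6 largest rises under the naming rule with antibiotic water and chow were in the oestrogen sulfotransferase gene Sult1e1, from 0.293 ± 0.284 to 79.4 ± 44.1 CPM (7.95 ± 1.02), Cyp2c70 (4.66 ± 0.88), Ddit4 (4.45 ± 0.97), Cyp2c69 (4.28 ± 0.96, not called by DESeq2) and Socs2 (4.27 ± 0.56). The 6 largest falls by the same rule were in G0s2, an inhibitor of lipolysis (-5.74 ± 0.95), the elongase gene Elovl3 (-5.48 ± 0.81), the peroxisomal thiolase gene Acaa1b (-4.65 ± 0.67), Clstn3 (-4.43 ± 0.71), Mup21 (-4.37 ± 0.79) and Klhdc7a (-4.36 ± 0.42). The drug-metabolising gene Cyp3a11 fell from 1574 ± 250.0 to 171 ± 30.2 CPM (-3.20 ± 0.53, adjusted p = 0.00106). Bile acid synthesis genes went both ways, 4 higher and 4 lower of 14 (5 and 5 adjusted over the list alone, camera adjusted p = 0.604). Cyp7b1 (2.59 ± 0.29) rose, Hsd17b4 (-0.91 ± 0.14), Amacr (-0.80 ± 0.14) and the sterol 12-alpha-hydroxylase gene Cyp8b1 (-2.22 ± 0.68) fell, and Cyp7a1 had a fold change of 1.34 ± 1.01 (adjusted p = 0.364).

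In all, 3138 genes passed with the chow meal, 1393 higher and 1745 lower with antibiotic water, of which 388 and 744 changed at least 2-fold. For 24.8% of all genes the groups did not overlap, against 2.86% by chance. Of 116 called genes named, 96 kept their call without each library in turn. The highest adjusted p of the other 20 is given with the library left out. Cyp8b1 (0.0798) and Mup17 (0.0732) had theirs without chow antibiotic replicate 1. Asns (0.203), Cyp4a14 (0.0898), Gls2 (0.107) and Pklr (0.0868) had theirs without chow antibiotic replicate 2. Chac1 (0.0637) had its own without chow antibiotic replicate 3. Atf3 (0.0848) and Tiparp (0.169) had theirs without chow antibiotic replicate 4. Arrdc4 (0.0557), Nqo1 (0.0732) and Saa4 (0.118) had theirs without chow control replicate 1. Reln (0.0715) had its own without chow control replicate 2. Btg2 (0.0542), Hspa1b (0.097) and Top2a (0.0865) had theirs without chow control replicate 3. Cyp2d9 (0.0685), Pfkfb3 (0.0629), Scd1 (0.0752) and Ugt2b1 (0.107) had theirs without chow control replicate 4. With 2 libraries per group, edgeR called 3319 genes on the low-share and 3 on the high-share side (2308 at an unadjusted p under 0.05). Of 3223 genes called in the former and tested in the latter, 90.9% had the same sign.

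**Figure D2:**
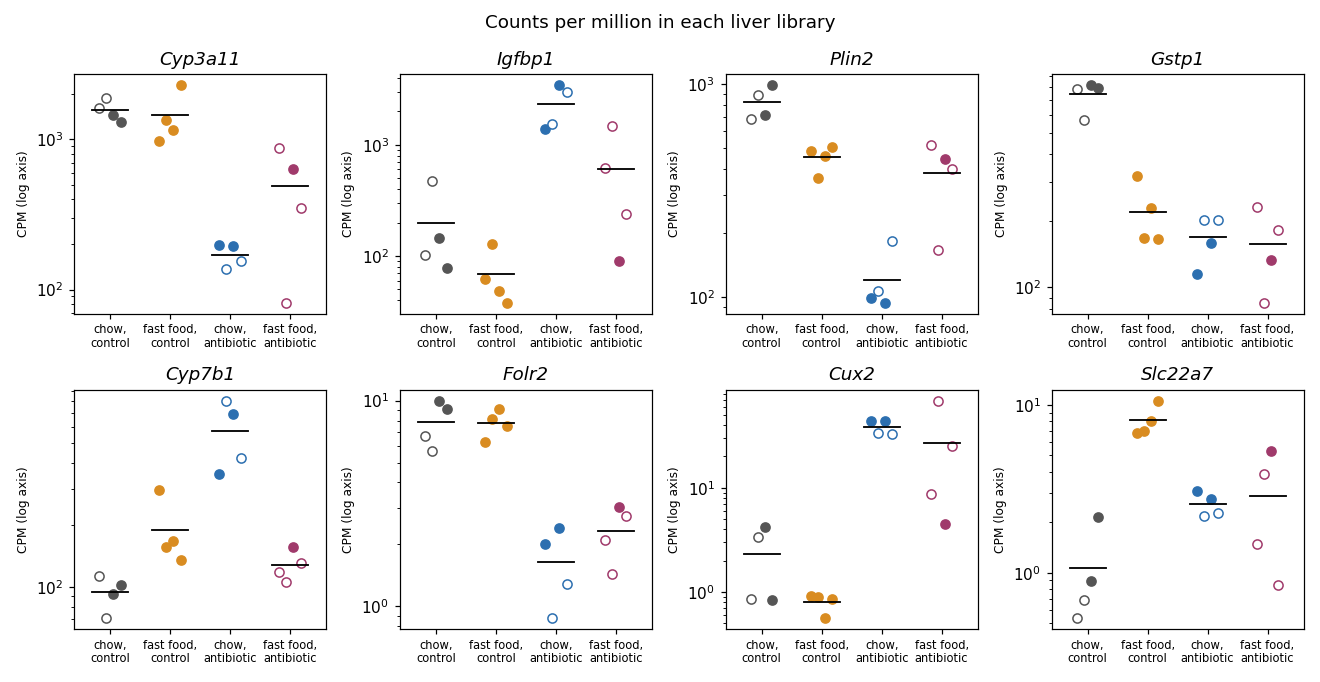
CPM (log axis) of 8 genes in each library, grouped by meal and water, with a line at the group mean, open circles for libraries with at least 1% of counts in rRNA-like features and filled circles for the rest. Cyp3a11 averaged 171 CPM in the chow antibiotic group and 1574 CPM in the chow control group, and Folr2 averaged 1.64 and 7.91 CPM.

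With the fast food meal, antibiotic water was followed by lower transcripts of Kupffer cell markers, interferon response and antigen presentation as lists. Of 13 Kupffer cell and macrophage markers 7 were lower, 11 adjusted over the list alone (camera adjusted p = 3.04e-08, adjusted p = 0.484 with an estimated correlation). Folr2 was 2.33 ± 0.714 CPM with antibiotic and 7.74 ± 1.18 CPM with control water (SD, n = 4 each), a log2 fold change of -1.72 ± 0.28 (edgeR adjusted p = 0.00733), and Timd4 (-1.18 ± 0.25), C1qb (-1.01 ± 0.25) and Vsig4 (-1.01 ± 0.25) fell. Interferon response genes were lower (4 of 26, 7 adjusted over the list alone, adjusted p = 1.72e-06, adjusted p = 0.484 with an estimated correlation), with Ifit2 (-1.34 ± 0.33), Ifit3 (-1.23 ± 0.33), Isg15 (-1.22 ± 0.32) and Irf7 (-1.04 ± 0.22). Antigen presentation genes were lower (1 of 14, 6 adjusted over the list alone, adjusted p = 4.91e-05, adjusted p = 0.484 with an estimated correlation), with H2-DMa (-1.72 ± 0.45). Of 2 B and plasma cell markers 1 was lower on either adjustment (median -1.90), a call that was lost over all genes without fast food control replicate 3, with DESeq2 and with either rRNA-like term.

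Male-biased liver genes were lower with antibiotic water and fast food (2 of 11, 3 adjusted over the list alone, camera adjusted p = 0.000253, adjusted p = 0.484 with an estimated correlation), with Cyp2d9 (-1.16 ± 0.23) and Ugt2b1 (-1.06 ± 0.29). The male-biased list passed camera whichever single library was left out. Mean male-biased scores differed by -1.14 with all libraries and -0.678 without fast food antibiotic replicate 2. The near-identical genes Mup17 (-4.29 ± 0.91), Mup16 (-2.89 ± 0.70), Mup7 (-2.55 ± 0.59) and Mup14 (-2.30 ± 0.50) were among the 6 largest falls under the naming rule, with Hectd2os (-1.82 ± 0.51) and Folr2. Cux2, a transcription factor gene with female-biased expression in liver, was 26.7 ± 29.4 CPM with antibiotic and 0.805 ± 0.164 CPM with control water (5.04 ± 0.84, adjusted p = 0.0101). The other large rises under that rule were in Plppr1 (2.55 ± 0.63), the leptin receptor gene Lepr (2.14 ± 0.58), Zfhx2 (1.96 ± 0.36), Zfp9 (1.95 ± 0.45) and Zbtb16 (1.84 ± 0.34).

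Among metabolic lists, fasting hormone response genes were higher with antibiotic water and fast food (3 of 12, 6 adjusted over the list alone, camera adjusted p = 0.0374, adjusted p = 0.484 with an estimated correlation), with Igfbp1 (3.14 ± 0.84), Foxo1 (0.84 ± 0.23) and Sds (0.80 ± 0.21). The fasting hormone list did not pass camera without fast food control replicate 4 (adjusted p = 0.134) or fast food antibiotic replicate 1 (0.152). Cholesterol synthesis was higher (adjusted p = 0.000709, adjusted p = 0.628 with an estimated correlation), with Dhcr7 (0.61 ± 0.17) called and 14 of 22 adjusted over the list alone. Cholesterol synthesis did not pass camera without fast food antibiotic replicate 2 (adjusted p = 0.0504). Mean cholesterol synthesis scores differed by 0.712 with all libraries and 0.317 without fast food antibiotic replicate 2. PPAR-alpha targets were lower (adjusted p = 0.003, adjusted p = 0.628 with an estimated correlation), with Acadm (-0.63 ± 0.17) called and 2 of 26 adjusted over the list alone. The PPAR-alpha list did not pass camera without fast food antibiotic replicate 2 (adjusted p = 0.154). Mean PPAR-alpha scores differed by -0.451 with all libraries and -0.118 without fast food antibiotic replicate 2. Bile acid synthesis was lower (2 of 14, 3 adjusted over the list alone, adjusted p = 0.00353, adjusted p = 0.484 with an estimated correlation), with Hsd3b7 (-0.62 ± 0.15) and Akr1c6 (-0.75 ± 0.21). The CAR and PXR list was lower (3 lower and 1 higher of 22, 4 and 1 adjusted over the list alone, adjusted p = 0.00372, adjusted p = 0.484 with an estimated correlation). Aldh1a1 (-1.08 ± 0.27), Ugt2b35 (-1.05 ± 0.23) and Ugt1a1 (-0.54 ± 0.15) fell and Por (0.52 ± 0.15) rose. Erythroid markers were lower (1 of 7 on either adjustment, adjusted p = 0.0383, adjusted p = 0.628 with an estimated correlation), with Car1 (-1.97 ± 0.45). The erythroid marker list did not pass camera without fast food control replicate 3 (adjusted p = 0.0597), fast food control replicate 4 (0.134), fast food antibiotic replicate 2 (0.349) or fast food antibiotic replicate 4 (0.122). Mean erythroid marker scores differed by -0.853 with all libraries, -0.371 without fast food antibiotic replicate 2 and -1.32 without fast food antibiotic replicate 3. Cyp3a11 (-1.57 ± 0.50, adjusted p = 0.0749), Fgf21 (0.78 ± 0.49, 0.337) and Scd1 (0.45 ± 0.93, 0.802) did not pass.

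With the fast food meal 790 genes passed, 497 higher and 293 lower with antibiotic water, with 3433 at an unadjusted p under 0.05 and no overlap for 18.4% of all genes. The rRNA-like share was low in all 4 control libraries and high in 3 of the 4 antibiotic libraries, so the high-share side holds libraries of 1 group only and the low-share side a single antibiotic library. With the split as a model term, or the share as a covariate, edgeR called 0 genes (1677 and 1578 at an unadjusted p under 0.05). DESeq2 without these terms called 1547. All 790 genes kept their sign with the split in the model, at a median of 0.777 of their fold change. The count was 117, 168 and 78 without fast food control replicates 1, 2 and 3, and 509, 378 and 186 without fast food antibiotic replicates 1, 2 and 4. Of the 36 called genes named, 2 (Cux2 and Folr2) kept their call without each library in turn. The highest adjusted p of the other 34 is given with the library left out. Adcy1 (0.125) and Lpin1 (0.102) had theirs without fast food antibiotic replicate 2. Acadm (0.123), Akr1c6 (0.126), Aldh1a1 (0.092), Car1 (0.0734), Dhcr7 (0.126), Plppr1 (0.107), Sds (0.116), Ugt2b1 (0.123) and Ugt2b35 (0.0651) had theirs without fast food control replicate 1. H2-DMa (0.0871), Hectd2os (0.114), Ifit2 (0.087), Ifit3 (0.116), Irf7 (0.058), Isg15 (0.0994) and Timd4 (0.0595) had theirs without fast food control replicate 2. C1qb (0.0866), Cyp2d9 (0.0535), Foxo1 (0.124), Hsd3b7 (0.0982), Igfbp1 (0.129), Lepr (0.134), Mup14 (0.0835), Mup16 (0.0987), Mup17 (0.0758), Mup7 (0.0879), Por (0.145), Ugt1a1 (0.119), Vsig4 (0.0871), Zbtb16 (0.0508), Zfhx2 (0.0508) and Zfp9 (0.0842) had theirs without fast food control replicate 3.

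The antibiotic effects with the 2 meals share no library. They had a correlation of 0.448 across 13180 genes, and 354 genes were called in both, 159 higher and 174 lower in both and 21 in opposite directions. Independent lists would share 52.5 rises and 38.8 falls. With the split as a model term or the share as a covariate edgeR called 0 genes in both, because it called 0 with the fast food meal, and DESeq2 without these terms called 678 in both. The correlation was 0.311 with the split as a model term, 0.386 with the covariate, 0.296 without the 3 libraries with high acute phase transcripts and 0.21 without a filter on low counts. Of the 3138 genes called with the chow meal, 77% had the same sign with the fast food meal, and the median ratio of the fast food to the chow fold change was 0.314. Of the 790 called with the fast food meal, 82.9% had the same sign with chow, and the median ratio of the chow to the fast food fold change was 0.549. Each ratio is taken over genes selected for the effect it divides by. Genes called with both meals included Cux2 (3.99 ± 0.76 with chow), Igfbp1, Lpin1 (3.55 ± 0.50 with chow and 1.84 ± 0.46 with fast food), Adcy1 (3.53 ± 0.65 and 2.54 ± 0.67), Plppr1 (3.24 ± 0.65 with chow) and Mup17 (-3.01 ± 0.89 with chow). Mup17 lost its call with chow without chow control replicate 1 or chow antibiotic replicate 1, 2 or 4 (edgeR adjusted p up to 0.0732), and without the 3 libraries with high acute phase transcripts (0.0514) and within the low-share (0.199) or high-share (0.274) chow libraries.

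On GRCm38 with GENCODE M21, the genes with levels given here are protein-coding and all but Igfbp1 and Lss lie on the minus strand. The annotation places Fgf21 (ENSMUSG00000030827) on chromosome 7 from 45613886 to 45615490, Lss (ENSMUSG00000033105) on chromosome 10 from 76531588 to 76557138 and Cyp7b1 (ENSMUSG00000039519) on chromosome 3 from 18071950 to 18243338. It places Cyp3a11 (ENSMUSG00000056035) on chromosome 5 from 145854426 to 145879964, Slc22a7 (ENSMUSG00000067144) on chromosome 17 from 46432183 to 46438457, Folr2 (ENSMUSG00000032725) on chromosome 7 from 101839988 to 101857194 and Cux2 (ENSMUSG00000042589) on chromosome 5 from 121856366 to 122050102. It also places Gstp1 (ENSMUSG00000060803) on chromosome 19 from 4035407 to 4037985, Sult1e1 (ENSMUSG00000029272) on chromosome 5 from 87575969 to 87591594 and Igfbp1 (ENSMUSG00000020429) on chromosome 11 from 7197782 to 7202546. Counts are sums over a whole gene, so no exon, untranslated region or isoform is resolved.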

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

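For fast food antibiotic replicate 2, the tests of the acute phase response and of rRNA-like reads were chosen only after the result was seen. So were the 3 tests on Kupffer cell, interferon and antigen presentation genes.

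Fast food antibiotic replicate 2 lay at 45.4 on the first principal component, far from the other 3 libraries of its group (-16.1 to -10). The other libraries of the group with many rRNA-like reads and low totals reached at most -10, which argues against these as the source. The acute phase response of that animal as the whole difference stays open, because this library lay 58.6 from the mean of the rest of its group and the raised libraries of the other groups lay 27.5 and 31.6 from theirs. Each library was held out and placed between the chow (0) and fast food (1) antibiotic means. The 200 to 333 genes used were called in antibiotic water, with the same sign and unadjusted p under 0.05 in control water. Replicate 2 lay at 0.115, the rest of its group at 0.769 to 0.906 and chow antibiotic libraries at -0.214 to 0.341. A chow antibiotic library under a fast food label may account for this. An animal not responding to the meal would give the same position, and these were not told apart.

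The 790 genes called between waters with the fast food meal coincide with the split in rRNA-like reads, since 3 of 4 antibiotic libraries and 0 of 4 control libraries had a high share. Over 776 of these genes, the high-minus-low difference within the chow groups had a median ratio of 0.298 to the antibiotic effect. The 95% bootstrap interval over genes, not animals, was 0.28 to 0.322, between the bounds of 0.2 (no part) and 0.5 (main part). Acute phase state is mixed in, as both raised chow libraries are high-share. Between these high and low chow libraries (4 each) edgeR, the only tool run here, called 0 genes (1477 at an unadjusted p under 0.05). Fast food antibiotic replicate 3, the low-share one, held a median of 0.4 of the effect in the rest of its group (936 genes, 90.8% with the same sign), but is 1 library. With the split in the model the 790 genes kept sign and a median of 0.777 of their fold change. Standard errors grew by a median factor of 1.12, and none passed. The antibiotic effect and the split cannot be told apart for these genes.

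Kupffer cell, interferon and antigen presentation genes were lower with antibiotic water under both meals. An even loss of non-hepatocyte cells is argued against with chow. The endothelial median lay 1.05 (log2) above the Kupffer cell one (95% bootstrap interval over members 0.711 to 1.94). An uneven loss stays open (median -0.32 for stellate, -0.25 for cholangiocyte markers). With chow the rRNA-like split is argued against because all 3 lists kept direction and camera call among low-share chow libraries (2 against 2, highest adjusted p = 1.91e-05) at the preset correlation. Among high-share ones (2 against 2) they kept both as well (highest adjusted p = 0.00568), with smaller differences of mean scores, -0.602 against -1.75 on the low-share side for interferon, -0.834 against -1.26 for Kupffer cell markers and -1.32 against -1.75 for antigen presentation. With fast food the split stays open. In a model with it the lists passed (highest adjusted p = 0.000166), but the 7 Kupffer cell, 4 interferon and 1 antigen presentation genes called without it all lost their calls. The list medians shrank from -0.89 to -0.68, -0.80 to -0.71 and -0.70 to -0.49, and the median standard errors grew from 0.261 to 0.319, 0.362 to 0.44 and 0.348 to 0.392. No list passed with an estimated correlation. A lower number or activity of resident macrophages with antibiotic water and chow is a hypothesis that may be followed up. Fewer B cells stay open beside it for the antigen presentation genes, since the median over 2 B and plasma cell markers was -2.60 with chow against -1.08 over Kupffer cell markers. Counts or staining of these cells were not analysed here.

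Among 192 groups of 4 values tested for a value far from the others, 13 had one, where chance gives about 9.6. In log2 CPM they were Gstp1 in chow control replicate 2 (9.16) and Cux2 in fast food control replicate 3 (-0.537), each the lowest of its group. In list scores they were fatty acid synthesis in fast food antibiotic replicate 3 (0.478), the acute phase (1.08) and immediate early (0.92) scores of chow control replicate 2, the interferon score of chow antibiotic replicate 4 (0.491), antigen presentation in chow control replicate 3 (1.54), the unfolded protein score of fast food antibiotic replicate 2 (0.56) and heat shock in fast food control replicate 4 (-0.19). Chow control replicate 1 had the fewest genes detected of its group (15294). On the second principal component chow antibiotic replicate 4 lay at -56.7 and fast food antibiotic replicate 1 at 12.1.

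The meal effect differed between the waters, by the edgeR test of the interaction, at 54 of the 192 named genes, against 519 of all 13180 genes. On the log2 scale it was more positive in antibiotic water for Fgf21 (4.86), G0s2 (4.58), Inhbe (4.26), Elovl3 (3.88), Chad (3.81), Klhdc7a (3.46), Acaa1b (3.27), Bdh1 (3.14), Fabp1 (3.00), Stap1 (2.85), Acot2 (2.75), Elovl5 (2.62), Plin2 (2.52), Lgals4 (2.29), Col15a1 (2.27), Hsph1 (2.11), Tbx3 (2.04), Nt5dc2 (1.94), Gabbr2 (1.91), Ccnd1 (1.82), Pgm3 (1.78), Gstp1 (1.66), Ccl25 (1.62), Slc22a5 (1.56), Cul7 (1.55), Prps2 (1.53), Dnaja1 (1.14), Gstm4 (1.12), Acacb (1.09), Nfe2l1 (1.06), Chdh (1.02) and Gstm1 (0.75). It was more negative for Sult1e1 (-5.50), Myom3 (-3.25), Cyp7b1 (-3.15), Slc22a7 (-2.65), Tes (-2.24), Rhbg (-1.98), Cyp2c50 (-1.79), Dmgdh (-1.79), Cyp2c54 (-1.76), Keg1 (-1.71), Got1 (-1.57), Bcl2l11 (-1.52), Omd (-1.47), Fmo2 (-1.40), Ugt2a3 (-1.33), Gpld1 (-1.29), Cry1 (-1.21), Prodh (-1.07), Slc27a5 (-1.02), Pcna (-0.94), Cyp27a1 (-0.94) and Otc (-0.75). Among lists, the median interaction was more positive for PPAR-alpha targets (0.89), antigen presentation (0.65) and heat shock genes (0.83). It was more negative for cholesterol synthesis (-1.04), bile acid synthesis (-0.39), choline and trimethylamine metabolism (-0.44), amino acid catabolism (-0.44), the acute phase (-0.31), the unfolded protein response (-0.78) and immediate early genes (-1.20).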

How the results depend on the processing

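The alternatives that left out 3 libraries or handled the rRNA-like share were chosen after seeing the data. Over 5377 values of named genes under an alternative, 4307 kept direction and side of the threshold, 969 kept direction and lost the threshold, 18 kept direction and passed it, and 83 changed sign, all of these in genes that had not passed in that comparison. Where a cause is not named, the cause was not tested.

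For the meal effect in control water (76 genes), DESeq2 gave 305, the 2 groups alone 365, omission of the 3 libraries 160, the covariate 22, the split term 17 and low-share libraries 154. For the meal effect in antibiotic water (1800), the 2 groups alone gave 229, omission of the 3 libraries 3206 and high-share libraries 1. For the antibiotic effect with chow (3138), 2 against 2 libraries gave 3 on the high-share and 3319 on the low-share side. The 3 libraries are all high-share, so the sides are not alike. For that with fast food (790), DESeq2 gave 1547, and the covariate and the split term gave 0 each (edgeR, 1578 and 1677 at an unadjusted p under 0.05). For the interaction (519), DESeq2 gave 1120, omission of the 3 libraries 1851, the covariate 143 and the split term 262. With other alternatives each count stayed within 1.5 times, omissions of a single library aside.

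Without single libraries the counts of genes ran, in the same order, over 11 to 42, 697 to 3042, 2301 to 3204, 78 to 933 and 164 to 1494, and the counts of lists over 9 to 11, 5 to 9, 11 to 13, 8 to 13 and 7 to 11. With an estimated correlation 0 lists passed camera in each comparison, against 10, 7, 12, 10 and 10 at the preset one and 2, 5, 11, 3 and 1 with fry. Without a filter on low counts 12 lists passed for the meal effect in antibiotic water, and with the covariate 6 passed for that in control water.

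Calls of lists were also lost at the preset correlation, with the adjusted p given. For the meal effect in control water these were stellate cell (0.0502) with RLE factors, bile acid synthesis (0.0897) and stellate cell (0.0737) without the 3 libraries, cholesterol synthesis (0.0802), bile acid synthesis (0.0942), CAR and PXR (0.0685) and stellate cell (0.196) with the covariate, bile acid synthesis (0.0995), CAR and PXR (0.0995) and stellate cell (0.247) with the split term, and bile acid synthesis (0.197), amino acid catabolism (0.104) and stellate cell (0.15) among low-share libraries. For that in antibiotic water they were amino acid catabolism (0.261) without the 3 libraries, amino acid catabolism (0.0628) and heat shock (0.0628) with the covariate, amino acid catabolism (0.0569) and heat shock (0.0569) with the split term, and unfolded protein (0.29) and heat shock (0.248) among high-share libraries. The antibiotic effect with chow lost unfolded protein (0.143) and erythroid (0.191) among high-share libraries. With fast food it lost cholesterol synthesis (0.0641), PPAR-alpha targets (0.221) and erythroid (0.348) without the 3 libraries, bile acid synthesis (0.0517), CAR and PXR (0.109) and erythroid (0.325) with the covariate, and CAR and PXR (0.0681) and erythroid (0.48) with the split term. The interaction lost antigen presentation (0.0536) with the block, bile acid synthesis (0.0996) without the 3 libraries, bile acid synthesis (0.0758) and heat shock (0.0892) with the covariate, and bile acid synthesis (0.1) and heat shock (0.0791) with the split term. With the covariate and the split term, erythroid markers passed newly for the meal effect in antibiotic water (0.0467 and 0.0297) and the unfolded protein list for the antibiotic effect with fast food (0.0144 and 0.00437).

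With the replicate number as a block, 65, 1547, 2916, 738 and 355 genes and 11, 9, 12, 10 and 9 lists passed. The numbers did not pair the samples, as libraries with the same number had correlations of deviations from -0.222 to 0.191 and 1 of 16 correlated best with its own number.

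The correlation between the meal effects in the 2 waters turned to -0.00164 without the 3 libraries and -0.0369 with the split term, from 0.119. The genes that changed sign are given with their log2 fold changes. Under the replicate block they were Cyp7a1 0.0591 (antibiotic, fast food) and 0.50 (meal, antibiotic water), G6pc -0.0508 (antibiotic, chow), Pck1 -0.0848 (antibiotic, chow), Saa1 -1.50 (meal, antibiotic water) and Scd1 -0.32 (antibiotic, fast food). Without the 3 libraries they were Cyp7a1 0.27 (antibiotic, fast food), Cyp8b1 0.00373 (antibiotic, fast food), Pdk4 0.0742 (antibiotic, chow) and -0.40 (meal, antibiotic water), Saa1 -0.51 (antibiotic, fast food), -1.27 (meal, antibiotic water) and 0.65 (meal, control water) and Srebf1 -0.0661 (meal, control water). With the covariate they were Cyp7a1 0.83 (antibiotic, fast food) and 0.38 (meal, antibiotic water), Nr0b2 0.0423 (antibiotic, fast food), Pck1 -0.00516 (antibiotic, chow) and -0.0896 (meal, control water), Pdk4 -0.0405 (meal, antibiotic water), Saa1 0.42 (meal, control water) and Srebf1 0.19 (antibiotic, fast food) and -0.19 (meal, control water). With the split term they were Cyp7a1 0.80 (antibiotic, fast food) and 0.31 (meal, antibiotic water), Pck1 -0.0180 (antibiotic, chow) and -0.0612 (meal, control water), Pdk4 -0.12 (meal, antibiotic water), Saa1 -0.63 (meal, antibiotic water) and 1.2 (meal, control water) and Srebf1 0.10 (antibiotic, fast food) and -0.18 (meal, control water). Among low-share libraries they were Cyp3a11 0.0547 (meal, control water), Pdk4 0.0708 (antibiotic, chow), Saa1 1.19 (meal, control water) and Srebf1 -0.21 (meal, control water). Among high-share antibiotic libraries they were Cyp7a1 0.61 (meal, antibiotic water), G6pc 0.22 (meal, antibiotic water), Nr0b2 0.49 (meal, antibiotic water) and Saa1 -0.37 (meal, antibiotic water), and among high-share chow libraries G6pc -0.52 (antibiotic, chow) and Pck1 -0.59 (antibiotic, chow). Another 41 changes of sign arose when a single library was left out, where values ranged over, for Cyp3a11 -0.44 to 0.0244 (meal, control water), Cyp4a14 -0.22 to 0.0227 (meal, control water), Cyp7a1 -0.45 to 0.28 (antibiotic, fast food) and -0.57 to 0.74 (meal, antibiotic water), Cyp8b1 -0.64 to 0.0186 (antibiotic, fast food) and -0.18 to 0.19 (meal, control water), G6pc -0.46 to 0.58 (antibiotic, chow), -0.13 to 0.35 (antibiotic, fast food) and -1.04 to 0.00129 (meal, antibiotic water), Nr0b2 -0.62 to 0.0726 (antibiotic, chow), -0.86 to 0.12 (antibiotic, fast food), -0.76 to 0.0854 (meal, antibiotic water) and -0.75 to 0.16 (meal, control water), Pck1 -0.38 to 0.40 (antibiotic, chow) and -0.0538 to 0.73 (meal, antibiotic water), Pdk4 -0.23 to 0.18 (meal, antibiotic water), Saa1 -1.17 to 4.35 (antibiotic, chow), -0.49 to 4.28 (antibiotic, fast food), -4.24 to 3.10 (meal, antibiotic water) and -2.33 to 0.61 (meal, control water), Scd1 -0.52 to 0.84 (antibiotic, fast food) and -0.95 to 0.0336 (meal, control water) and Srebf1 -0.0769 to 0.18 (meal, control water).

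The 7 libraries with a high rRNA-like share also had the lowest totals (8954378 to 15094803, against 18102482 to 18954655 in the other 9), so genes of low count are measured less precisely in them.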

Other observations

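Among other gene groups with antibiotic water and the chow meal, fatty acid synthesis genes went both ways (5 lower and 1 higher of 17, 5 and 3 adjusted over the list alone, camera adjusted p = 0.604). Elovl5 (-2.90 ± 0.44), Fads2 (-1.98 ± 0.37), Me1 (-0.64 ± 0.14) and Scd1 (-3.52 ± 1.03) fell. Of 14 glycolysis genes 3 were higher and 1 lower (3 and 3 adjusted over the list alone, adjusted p = 0.851), with Gpd1 (-1.20 ± 0.20), Pklr (1.34 ± 0.43), Pfkfb3 (2.02 ± 0.58) and Arrdc4 (1.26 ± 0.36). Bile acid and sterol transport genes went both ways (4 higher, 4 lower of 15 on either adjustment, adjusted p = 0.941), their median being 0.11, their mean -0.16 and camera's direction down. The sterol exporter genes Abcg5 (-1.08 ± 0.18) and Abcg8 (-0.85 ± 0.22) and the phospholipid exporter gene Abcb4 (-1.15 ± 0.19) fell and Klb (0.69 ± 0.17) rose. Clock genes went both ways (3 higher, 4 lower of 18 on either adjustment, adjusted p = 0.558), with a median of 0.28, a mean of -0.0268 and camera's direction up. Cry1 (1.31 ± 0.21) and Per1 (1.47 ± 0.24) rose and Bhlhe41 (-2.41 ± 0.47) fell.

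Xenobiotic genes of the CAR and PXR list also went both ways with antibiotic water and chow (5 higher, 8 lower of 22, 5 and 9 adjusted over the list alone, camera adjusted p = 0.558), with Por (1.03 ± 0.15), Cyp2c54 (1.49 ± 0.24), Cyp2c50 (1.49 ± 0.25) and Aldh1a1 (-1.53 ± 0.27). NRF2 genes did so as well (3 higher, 4 lower of 13, 3 and 5 adjusted over the list alone, adjusted p = 0.604), with Gclc (-1.27 ± 0.16), Gstm4 (-1.26 ± 0.20), Ephx1 (-1.23 ± 0.20) and Gstm2 (1.23 ± 0.22). Aryl hydrocarbon receptor genes (3 higher, 1 lower of 7 on either adjustment, adjusted p = 0.484) included Cyp1b1 (1.05 ± 0.27), Cyp1a2 (-1.32 ± 0.34), Nqo1 (0.47 ± 0.15) and Tiparp (2.25 ± 0.75). Of 12 stellate cell markers 4 were lower and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.21), with Col3a1 (-2.28 ± 0.39), Col1a2 (-1.23 ± 0.23), Col1a1 (-1.76 ± 0.49) and Reln (-0.59 ± 0.19). Cell cycle genes (2 lower, 1 higher of 12 on either adjustment, adjusted p = 0.558) included Ccnd1 (-2.37 ± 0.32), Top2a (-1.79 ± 0.56) and Pcna (0.67 ± 0.17). Pericentral genes (4 higher, 2 lower of 13, 4 and 3 adjusted over the list alone, adjusted p = 0.861, median and mean below 0 and camera's direction up) included Tbx3 (-1.61 ± 0.29), Slc1a2 (0.57 ± 0.13), Cyp2c29 (1.22 ± 0.30) and Gulo (0.61 ± 0.16). Periportal genes (3 of 12 higher on either adjustment, adjusted p = 0.484) included Ass1 (0.67 ± 0.17) and Gls2 (0.43 ± 0.14). Male-biased genes (3 lower, 1 higher of 11, 6 and 1 adjusted over the list alone, adjusted p = 0.0638) included Cyp2d9 (-0.80 ± 0.22), Ugt2b1 (-0.90 ± 0.28) and Serpina1e (1.32 ± 0.26). Markers of pancreas and intestine, too few for a test of the list, included Lgals4 (-1.43 ± 0.27), Fabp2 (-2.27 ± 0.44) and Cela2a (6.75 ± 1.26).

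Other splits of the same libraries were compared with the real ones. For genes, chance can be excluded in each comparison of 2 groups, as 1 of 35 splits, the real one, gave a count as large. That is the lowest share that 35 splits can give. The counts were 76 against a highest other of 1 (meal, control water), 1800 against 1050 (meal, antibiotic water), 3138 against 3 (antibiotic, chow) and 790 against 0 (antibiotic, fast food). The split with 1050 genes exchanged fast food antibiotic replicate 2 with a chow antibiotic library. For the interaction 2 of 100 splits, the real one included, gave a count as large as 519. The highest other, 2449, points to a structure of the samples, which was not tested, so these splits cannot decide on chance. For lists, chance stays open for the antibiotic effect with chow (only 12 against 11, 1 of 35 splits). It cannot be excluded for the meal effect in control water (10 against 11, 2 of 35) and in antibiotic water (7 against 14, 17 of 35), the antibiotic effect with fast food (10 against 13, 7 of 35) or the interaction (10 against 16, 17 of 100).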
